A study of Mus musculus with 6 samples.

How the data were processed

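The series holds bulk RNA-seq of mouse macrophages in 2 groups of 3 libraries, control and SAHH-KO, all from cells given interferon-γ and lipopolysaccharide. Per the labels' protocols, the cells were peritoneal macrophages elicited with thioglycollate, collected after 4 days and purified by 6 h of adherence, and each library was made from 1.3 µg of total RNA with a SMARTer mRNA kit. The labels call the control cells shControl in one field and WT in another, and they call the other group SAHH-KO in one field and a knockdown in another. The name SAHH-KO is used here for the group without a choice between these. Nothing in the labels says whether the 3 replicates of a group came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical.

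The authors deposited 1 table of FPKM values (fragments per kilobase of gene, scaled to library size) with 54532 genes, 1 column per library, and each gene's Ensembl identifier, coordinates, length and biotype. Per the submitters' processing notes the tools were FastQC, Trim Galore, STAR and featureCounts and the builds GRCm38 and mm10, with no versions and no settings. Whether strand was used in counting, and how the counts became FPKM, is not given in the sources used here. Of the gene identifiers, 54495 are in the GENCODE M21 annotation of GRCm38, and 53585 have the same start and end there.

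The FPKM values times gene length were whole multiples of 1 step in each library: 100% of the values above 0 came out whole within 0.01 of a read. The reads assigned to genes and the library size the authors divided by were worked out from that step. The control libraries held 15540442 to 16676534 assigned reads and the SAHH-KO libraries 15856261 to 17748745. The deposited values rest on library sizes that equal median-of-ratios size factors, with a ratio of 1 between them in each library. These sizes were on average 1.06 times the assigned reads in control and 0.95 times in SAHH-KO. For a gene of 1 kb, 3 reads were worth 0.168 to 0.197 FPKM, which was taken as the floor per library. The floors cover counting error only, since the reads carry no molecular identifiers.

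Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested, which left 10362. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on log2(FPKM + 1), with the group as the only term, two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. All adjusted p-values for genes come from that model. Log2 fold changes, and counts of genes past a fold threshold, are on the log2(FPKM + 1) scale. It understates the change of genes with low values, so group means in FPKM or their ratio are given as well. For single genes, changes written as a fold or as a share of the control mean are ratios of group means in FPKM. Had the table held raw counts, another test was planned as the main one. It holds FPKM alone, so the tools for counts that were meant as alternatives were not run.

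Before the data were examined, 43 gene lists, the alternatives and the rule for naming genes were fixed. Of 1136 list symbols, 1132 matched the table, 5 of them through RefSeq synonyms (GRCm38.p6). The 34 lists with at least 5 tested members were tested with camera from limma, with its preset correlation of 0.01, and adjusted over the lists. Camera was repeated with a correlation estimated from the data, and fry was run as well, which asks whether the genes of a list move on balance one way and does not compare the list with other genes. The genes named are Ahcy, and the 12 largest rises and 12 largest falls among genes past the threshold. For these 24 genes a mean of at least 5 FPKM in the higher group and no overlap between the groups were required, and clone names, predicted genes and pseudogenes were left out. Also named are up to 4 members of each list with the smallest p past the test, and Il1b, Il6, Tnf, Il12b, Nos2, Cxcl10, Ccl2, Dnmt1, Dnmt3a, Tet2, Ezh2 and Kdm6b. The rule gave 159 genes, some of which are not reported here. Any other gene is said to have been chosen after its values were seen.

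Replicates were compared first. No pair of libraries held identical values, and within groups the chi-square of the recovered reads per degree of freedom lay between 3.97 and 29.1, so each library counted as 1 replicate. That spread does not tell separate cultures from separate libraries of the same RNA. Both groups carry the replicate numbers 1 to 3, and the deviations of equally numbered libraries from their group means did not go together in each pair, so the fit has no block.

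The exons and the transcript sequence of the named genes were compared with all other genes of M21. Counting can split reads between near-identical copies, and 9 named genes shared at least 25% of their 50-base words with a copy: Ahcy, Bcl2a1d, C1ra, Cycs, Ifit3, Pgam1, Rps23, Rps27 and mt-Nd3. Exon bases shared with another gene reached 10% in 12 named genes, 10 of them on the opposite strand: Ccna2, Cxcl11, Fdft1, Gnas, Hmgcs1, Il1a, Il27, Rfx5, Suv39h1 and Tgm2. Pnp and Serpinb2 shared theirs with a gene on the same strand. Levels of all these genes are uncertain to that extent.

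The code was tested on simulated reads for the real genes, with the real means and library sizes and 200 genes changed by known folds, of which those tested lay among 10280 genes. The test recovered 21.5% of the genes changed by 1.5-fold, 90.8% of those changed by 2-fold and 100% of those changed by 4-fold. Each changed gene that was called had the right direction. Of its calls, 9.21% were genes that had not been changed, above the nominal share of 0.05. On the same simulated reads 4.43% of the calls of voom, a limma method that weighs each value by its read depth, had not been changed. All genes were simulated with the same fixed spread between libraries, which was not estimated from these data. Far fewer genes were changed than were called in the data, so these shares need not hold for the real comparison. Voom on the recovered reads was added as an alternative after the data were seen. Total-count scaling, which replaces the authors' library sizes by the assigned reads, was also added then. Alternatives fixed beforehand covered the pseudocount, the filter, scaling as TPM, by median-of-ratios factors and by quantiles, a replicate block, the variance model, library weights and each library left out in turn. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.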

Results

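Gene expression was measured in macrophages labelled as thioglycollate-elicited mouse peritoneal cells, after 8 h with interferon-γ at 2 ng/mL and lipopolysaccharide at 10 ng/mL, a pair of stimuli that drives classical, inflammatory activation. The values of 3 control libraries were set against those of 3 libraries of the SAHH-KO group, in which S-adenosylhomocysteine hydrolase was targeted. This enzyme, encoded by Ahcy, breaks down S-adenosylhomocysteine, the product and inhibitor of methyltransferases. The title of the series names SAHH deficiency, clonal haematopoiesis, atherosclerosis and epigenetic regulation of inflammation, so the comparison asks how the inflammatory transcriptome differs when the enzyme is low. No unstimulated libraries are among those analysed here, so every value describes stimulated cells. Between 15540442 and 16676534 reads were assigned to genes per control library and between 15856261 and 17748745 per SAHH-KO library, and 10069 to 10259 genes reached 1 FPKM in a library.

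Ahcy transcript was 4.22-fold lower in SAHH-KO. The mean was 24.3 ± 1.59 FPKM (SD, n = 3) in control and 5.75 ± 0.419 FPKM in SAHH-KO, and the single libraries read 25.8, 22.6 and 24.4 against 5.51, 5.50 and 6.23 FPKM. Its log2 fold change was -1.90 (SE 0.0873, limma adjusted p = 1.44e-06). Ahcy (ENSMUSG00000027597) is a protein-coding gene on chromosome 2 of GRCm38, bases 155059310 to 155074497 on the minus strand, and its longest annotated transcript has 10 exons. The level carries a limit of annotation. Gm4737 (ENSMUSG00000048087), a single-exon gene on chromosome 16, bases 46152985 to 46155077, shares 90.4% of its 50-base words with Ahcy transcripts, and 66.0% of the Ahcy words occur in Gm4737. It and the related genes named below were looked at after the values were seen. Gm4737 was counted at 66.2 ± 2.51 FPKM in control and 18.0 ± 2.50 FPKM in SAHH-KO, a 3.69-fold fall (log2 fold change -1.83, SE 0.104, adjusted p = 4.10e-06). Reads of these genes cannot be assigned to one of them with certainty. Summed over both, they fell from 207 ± 9.09 to 53.7 ± 5.18 CPM (reads scaled to the effective library size), and 67.1% of them had been placed on Gm4737 in control and 69.8% in SAHH-KO. Of the related genes, Ahcyl1 rose from 44.7 ± 2.04 to 60.6 ± 6.13 FPKM (adjusted p = 0.00450), and Ahcyl2 lay at 3.37 ± 0.157 and 3.88 ± 0.337 FPKM (adjusted p = 0.171).

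**Figure D1:**
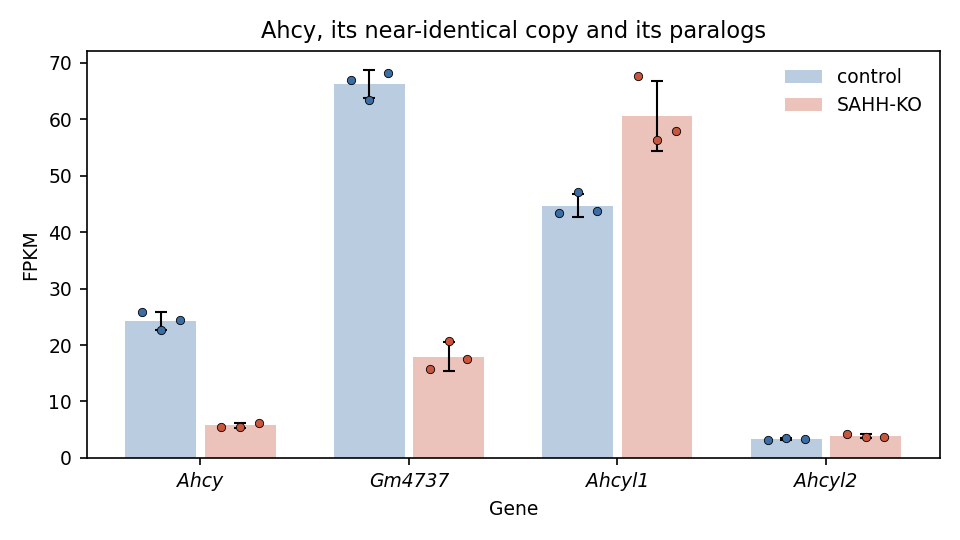
FPKM (vertical axis, starting at 0) of Ahcy, its near-identical copy Gm4737 and its paralogs Ahcyl1 and Ahcyl2. Bars are the mean of 3 libraries, error bars the SD and points single libraries, with control in blue and SAHH-KO in red. Ahcy lay between 22.6 and 25.8 FPKM in control and between 5.50 and 6.23 FPKM in SAHH-KO.

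The groups differed across much of the transcriptome. Of 10362 genes tested, 2736 were higher and 2782 lower in SAHH-KO, together 53.3%. Of these 5518 genes, 689 rose and 405 fell by at least 2-fold. Values of the groups did not overlap for 6454 genes, 62.3% of those tested, where chance gives 10%. The first principal component held 84.4% of the variance and separated the groups. The balance of higher to lower genes rests on the scaling of the libraries. With values rescaled to TPM the counts were 2006 higher and 3894 lower, and with scaling by assigned reads, tried after the data were seen, 2033 higher and 3905 lower. These scalings move the median of all tested genes by -0.16 and -0.14 on the log2 scale, and small changes below are to be read relative to that shift.

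Lists of genes fixed before the data were examined were tested next. Of 34 lists, 10 were called higher and 2 lower in SAHH-KO. With a correlation estimated from the data, 2 of these calls held, those of the interferon-stimulated genes and of the interferon-γ-induced genes. For each of the other 10 the adjusted p under the estimated correlation is given with the list. Another split of the 6 libraries into 3 and 3 called 13 lists, but that split, control replicates 1 and 3 with SAHH-KO replicate 1 against the others, keeps part of the group difference. Counts of members adjusted over the list alone were equal to those over all genes in 32 of the 43 lists and are given beside the others.

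**Figure D2:**
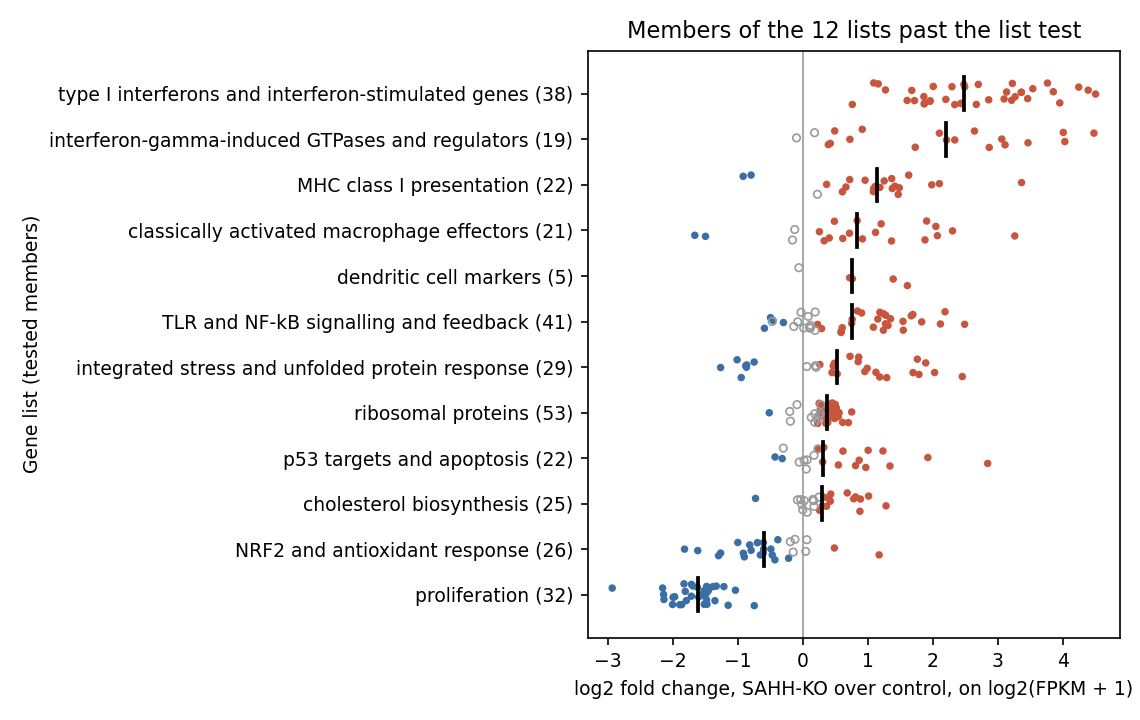
Log2 fold change of SAHH-KO over control on log2(FPKM + 1) (horizontal axis) for each tested member of the 12 lists called, with the number of members in brackets. Filled points passed the limma test (red higher, blue lower), open grey points did not, and black bars are medians, which run from -1.61 for the proliferation genes to 2.49 for the interferon-stimulated genes.

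Interferon-stimulated genes were the group with the largest rise. All 38 tested members of the list were higher in SAHH-KO, with a median log2 fold change of 2.49 (list adjusted p = 2.85e-27, and adjusted p = 0.0147 with an estimated correlation). The antiviral genes Ifit2, Rsad2 and Cmpk2 rose from 8.47 ± 1.09, 16.8 ± 0.734 and 12.7 ± 0.704 FPKM to 214 ± 21.7, 375 ± 53.5 and 258 ± 5.69 FPKM (log2 fold changes 4.50, 4.39 and 4.24, adjusted p = 8.37e-08, 8.37e-08 and 3.24e-08). Ifit3, which shares reads with Ifit3b, rose 18.2-fold, Isg20, an exonuclease, 20.3-fold, and Isg15, a ubiquitin-like modifier, 10.4-fold. Stat2, a transcription factor of the type I interferon pathway, went from 4.52 ± 0.172 to 63.3 ± 6.07 FPKM.

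Among genes induced by interferon-γ, 17 of 19 tested were higher and none was lower (median 2.21, list adjusted p = 2.56e-10, and adjusted p = 0.0323 with an estimated correlation). Without the filter on low genes the median was 0.80. The counts cover tested members only, and Ciita of this list had 0 reads in all libraries. Cxcl9, of the chemokine list, had 0 reads in control and 3 in SAHH-KO. Both were looked at after the values were seen. The guanylate-binding proteins Gbp5, Gbp2, Gbp2b and Gbp3, which act in defence against intracellular microbes, stood at 0.818 ± 0.194, 1.79 ± 0.433, 1.49 ± 0.257 and 3.56 ± 0.0999 FPKM in control. In SAHH-KO they reached 39.95 ± 8.69, 44.2 ± 2.11, 39.0 ± 2.99 and 38.4 ± 0.853 FPKM, with log2 fold changes of 4.48, 4.03, 4.01 and 3.11 and adjusted p-values of at most 3.15e-07. Irgm2, an immunity-related GTPase, rose 9.30-fold.

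Genes of MHC class I presentation were higher for 19 and lower for 2 of 22 tested members, and for 20 and 2 adjusted over the list alone (median 1.15, list adjusted p = 3.85e-08). The list call was lost with an estimated correlation (adjusted p = 0.177). Tap1, a subunit of the peptide transporter, rose from 4.42 ± 0.485 to 54.8 ± 3.11 FPKM, and Nlrc5, the transactivator of these genes, from 4.98 ± 0.813 to 24.5 ± 0.854 FPKM. The immunoproteasome subunit gene Psmb10 rose 2.73-fold and H2-T24 2.85-fold. The lower members, chosen after their values were seen, were Calr and Pdia3, chaperones of the endoplasmic reticulum. Class II presentation genes split: 6 of 10 tested were higher and 2 lower, and the list was not called (adjusted p = 0.245). Among the members not tested, H2-Aa, H2-Eb1 and Ciita had 0 reads and H2-Ab1 had 5 over all 6 libraries. These were looked at after the values were seen, and they were near 0 in both groups, so the counts describe other members of the list. Cd40 rose from 18.2 ± 2.03 to 136 ± 11.6 FPKM, Cd74, the invariant chain, from 114 ± 8.15 to 513 ± 139.6 FPKM and Rfx5 from 0.915 ± 0.178 to 4.26 ± 0.617 FPKM. Cd86, a costimulatory ligand, fell from 1.68 ± 0.186 to 0.214 ± 0.0547 FPKM, and the other lower member was Ifi30, named after its values were seen.

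Toll-like receptor and NF-κB genes were mostly higher, with 26 of 41 tested higher and 4 lower, or 27 and 5 adjusted over the list alone (median 0.75, list adjusted p = 1.67e-06, and adjusted p = 0.0973 with an estimated correlation). Nfkbiz and Nfkbie, genes of the IκB family, rose 4.41-fold and 6.48-fold, Traf1 2.99-fold, and Tlr3, a receptor for double-stranded RNA, from 1.33 ± 0.275 to 7.27 ± 0.513 FPKM. Of the effectors of classically activated macrophages 17 of 21 were higher and 2 lower (median 0.84, list adjusted p = 2.57e-05, and adjusted p = 0.0656 with an estimated correlation). Slfn4 rose from 79.6 ± 6.09 to 772 ± 45.2 FPKM, Saa3, an acute-phase protein gene, 5.06-fold, Fcgr4 4.27-fold and Lcn2 2.62-fold. The lower members, Slc7a2 and the interleukin-1 receptor antagonist gene Il1rn, were chosen after their values were seen. Nos2, which encodes inducible nitric oxide synthase, rose from 79.4 ± 9.18 to 174 ± 17.2 FPKM (log2 fold change 1.12, SE 0.108, adjusted p = 6.77e-05). Genes of alternative activation were not called as a list (adjusted p = 0.245), with 3 of 11 tested higher and 2 lower. Ccl22, Klf4 and Tgm2 were the higher ones (3.72-fold, 5.07-fold and 1.90-fold), and the lower ones were Cd200r1, at 0.528 of its control mean, and Clec7a, named after its values were seen.

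Cytokine genes moved in both directions. In the list of pro-inflammatory cytokines 10 of 18 tested were higher and 6 lower, and in that of chemokines 7 of 13 were higher and 4 lower. Neither list was called (adjusted p = 0.0939 and 0.172). Il27 rose from 30.3 ± 0.343 to 353 ± 13.6 FPKM, Csf1 from 0.443 ± 0.0998 to 12.7 ± 2.42, Il18 from 1.76 ± 0.655 to 20.4 ± 1.77 and Lif from 126 ± 8.95 to 378 ± 35.3 FPKM. Ccl5 reached 1846 ± 175 FPKM from 129 ± 10.9, and the interferon-inducible chemokines Cxcl10 and Cxcl11 reached 218 ± 27.7 and 6.28 ± 1.24 FPKM from 22.6 ± 0.998 and 0.140 ± 0.0734. Tnf, already at 2065 ± 67.7 FPKM in control, rose to 3043 ± 171 (log2 fold change 0.56, adjusted p = 0.000382), and Il6 rose from 1.38 ± 0.306 to 4.56 ± 1.06 FPKM (1.21, adjusted p = 0.000378). The interleukin-1 genes went the other way. Il1a fell from 45.1 ± 8.50 to 9.34 ± 3.602 FPKM (log2 fold change -2.21, SE 0.260, adjusted p = 0.000201). Il1b fell from 115 ± 14.1 to 43.5 ± 22.6 FPKM (-1.54, SE 0.375, adjusted p = 0.00879), with wide spread in SAHH-KO, and without the filter on low genes it missed the threshold (adjusted p = 0.0566). Ccl2, which draws monocytes, fell from 2773 ± 274 to 1220 ± 210.4 FPKM (-1.19, SE 0.136, adjusted p = 0.000168). The other lower members of the cytokine list, Csf2, Csf3, Il1f9 and Hmgb1, were named after their values were seen, and Csf3 missed the threshold without the filter (adjusted p = 0.0533). Il12b lay at 0.0207 ± 0.0358 and 0.0663 ± 0.0661 FPKM and was not tested.

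**Figure D3:**
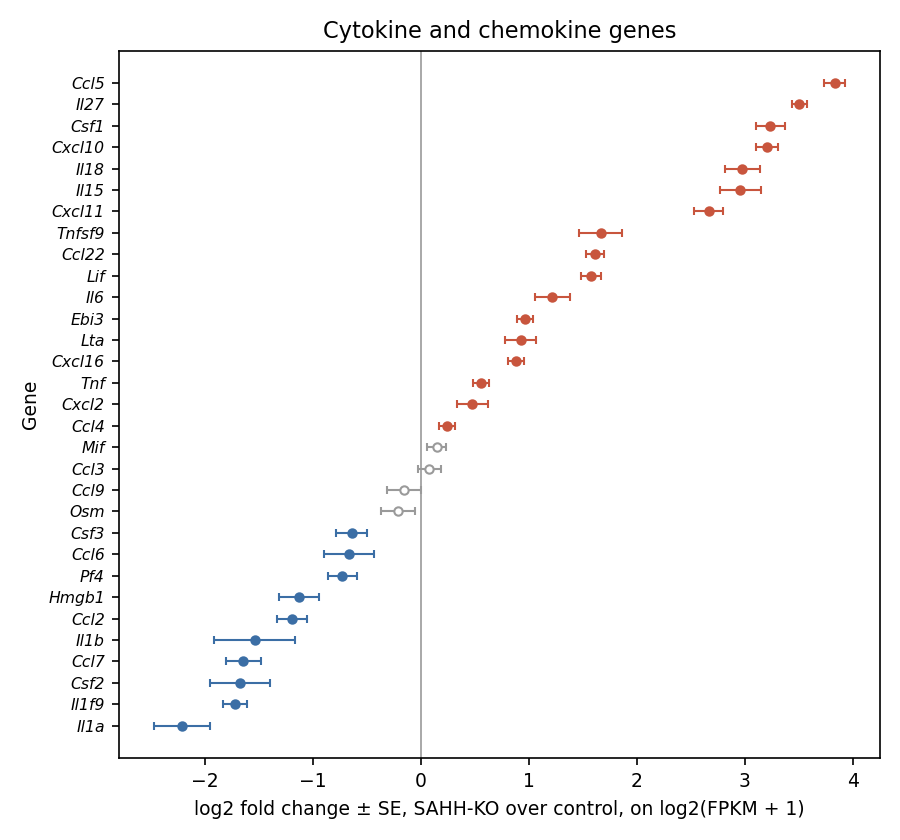
Log2 fold change of SAHH-KO over control with its SE on log2(FPKM + 1) (horizontal axis) for the 31 tested cytokine and chemokine genes. Filled points passed the limma test (17 higher in red, 10 lower in blue) and open grey points, 4 genes, did not.

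Genes of the inflammasome and pyroptosis were higher for 11 and lower for 5 of 21 tested members, and the list was not called (adjusted p = 0.0557). Without control replicate 2 it was called (adjusted p = 0.0260), as it was under other filters and with TPM or assigned-read scaling. Nlrp3, an inflammasome sensor, rose from 206 ± 10.9 to 378 ± 25.4 FPKM, Gsdmd, the pore-forming gasdermin, 2.10-fold and Casp4 2.53-fold. The list also holds Il1b, which was lower, and Il18, which was higher, both given with the cytokines above. Pycard, which encodes the inflammasome adaptor ASC and was looked at after the values were seen, had 11 reads over all 6 libraries and was not tested.

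Proliferation genes fell together. All 32 tested members were lower in SAHH-KO, with a median log2 fold change of -1.61 (list adjusted p = 2.68e-17), and the list call was lost with an estimated correlation (adjusted p = 0.177). Rrm2, a subunit of ribonucleotide reductase, fell from 42.6 ± 2.19 to 4.803 ± 1.14 FPKM, the cyclin gene Ccna2 from 24.5 ± 0.337 to 4.74 ± 0.527 and the mitotic kinase genes Plk1 and Aurka from 36.9 ± 2.81 and 38.1 ± 1.36 to 8.51 ± 0.638 and 10.22 ± 1.071 FPKM. Hmmr, a spindle-associated gene, fell from 14.5 ± 2.92 to 2.42 ± 0.596 FPKM.

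Genes of 3 stress programmes changed. Among genes of the integrated stress and unfolded protein response 19 of 29 tested were higher and 7 lower, with 21 and 7 adjusted over the list alone (median 0.53, list adjusted p = 0.00112, and adjusted p = 0.102 with an estimated correlation). Trib3, Ddit3, Sesn2 and Chac1, which lie downstream of the transcription factor ATF4, rose 6.03-fold, 4.43-fold, 3.65-fold and 3.54-fold. The lower members, named after their values were seen, were Slc7a11 and 6 genes of protein folding in the endoplasmic reticulum, Hsp90b1, Dnajb9, Dnajc3, Sdf2l1, Pdia4 and Creld2. Dnajb9 missed the threshold without the filter on low genes (adjusted p = 0.0537). Antioxidant genes driven by NRF2 were lower for 19 and higher for 2 of 26 tested (median -0.60, list adjusted p = 1.52e-05, and adjusted p = 0.0656 with an estimated correlation). Srxn1 fell from 43.9 ± 1.49 to 13.8 ± 1.89 FPKM, the cystine transporter gene Slc7a11 from 27.2 ± 1.83 to 10.7 ± 0.771, Gclm, a subunit of the enzyme that starts glutathione synthesis, from 11.5 ± 1.20 to 4.08 ± 0.377 and Nqo1 from 2.60 ± 0.594 to 0.0129 ± 0.0223 FPKM. Sod2 and Keap1, the higher members, were named after their values were seen. Targets of p53 and apoptosis genes were higher for 13 and lower for 2 of 22 tested (median 0.32, or 0.17 with TPM and 0.16 with assigned-read scaling, list adjusted p = 0.00267, and adjusted p = 0.102 with an estimated correlation). The cell-cycle inhibitor gene Cdkn1a rose from 43.9 ± 3.26 to 169 ± 5.49 FPKM, Bbc3, which encodes the death-promoting protein PUMA, from 6.80 ± 2.24 to 53.9 ± 9.53 FPKM, Eda2r 8.73-fold and Bcl2a1d, which has near-identical copies, 1.83-fold.

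In the pathways around S-adenosylhomocysteine changes were mixed. Of the methionine cycle and one-carbon genes 6 of 24 tested were higher and 12 lower, or 13 lower adjusted over the list alone, and the list was not called (adjusted p = 0.207). Cth, which makes cysteine from cystathionine, rose from 17.5 ± 2.73 to 89.6 ± 5.93 FPKM (log2 fold change 2.30, SE 0.113, adjusted p = 2.07e-06), while Shmt1 fell from 7.15 ± 0.427 to 2.54 ± 0.297 FPKM. Of 11 adenosine genes 3 were higher and 2 lower (list adjusted p = 0.814). Adora2a, an adenosine receptor gene, rose 8.46-fold, Pnp 2.67-fold, and Adk, the adenosine kinase gene, fell from 6.45 ± 1.13 to 4.03 ± 0.420 FPKM.

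DNA methylation genes were lower for 8 and higher for 2 of 16 tested, or lower for 9 adjusted over the list alone, without a call of the list (adjusted p = 0.152). The maintenance methyltransferase gene Dnmt1 fell from 22.8 ± 2.71 to 11.9 ± 0.780 FPKM (log2 fold change -0.89, SE 0.101, adjusted p = 0.000172), its partner Uhrf1 from 19.2 ± 2.45 to 6.85 ± 1.09 and Dnmt3a from 14.5 ± 1.19 to 8.52 ± 0.374 FPKM (-0.70, adjusted p = 0.000253). Tet2, a 5-methylcytosine dioxygenase gene, rose from 8.56 ± 0.565 to 12.8 ± 0.917 FPKM (0.53, adjusted p = 0.00137). Uhrf1 and Dnmt1 are also expressed with the cell cycle, whose genes fell in the same libraries. Whether their falls, or those of Ezh2 and Suv39h1 given below, are separate from the fall of cell-cycle genes was not tested. Histone and arginine methyltransferases went both ways, with 9 of 37 higher and 10 lower (list adjusted p = 0.784). Setdb2 rose 4.91-fold and Nsd3 2.58-fold, while Suv39h1 fell to 0.413 and Ezh2, the polycomb methyltransferase, to 0.524 of its control mean (adjusted p = 0.000379). Histone demethylases were higher for 7 and lower for 4 of 22, or higher for 6 adjusted over the list alone (list adjusted p = 0.259). Kdm4a rose 2.72-fold, Kdm5b 3.17-fold, Kdm7a 1.802-fold and Kdm6b from 10.7 ± 2.82 to 19.3 ± 0.985 FPKM (adjusted p = 0.00233). RNA methylation genes were lower for 8 and higher for 1 of 21, or lower for 6 adjusted over the list alone (list adjusted p = 0.245), with Nsun2 at 56.1 ± 2.33 and 37.8 ± 2.83 FPKM and Ythdf1 at 21.1 ± 0.859 and 28.1 ± 0.791 FPKM.

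Genes recurrently mutated in clonal haematopoiesis were higher for 7 and lower for 9 of 29 (list adjusted p = 0.800). Jak2, a kinase gene, rose from 16.4 ± 2.14 to 56.9 ± 9.88 FPKM, Trp53 from 37.9 ± 1.61 to 58.9 ± 1.44 and Bcorl1 2.27-fold.

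In lipid and matrix genes, cholesterol biosynthesis was called higher, with 14 of 25 tested higher and Ebp alone lower (median 0.30, or 0.17 with TPM and 0.16 with assigned-read scaling, list adjusted p = 0.00493, and adjusted p = 0.177 with an estimated correlation). Fdft1, squalene synthase, rose from 7.94 ± 0.415 to 20.8 ± 1.02 FPKM, Mvd 2.07-fold and Hmgcs1 1.94-fold, and Ebp fell to 0.574 of its control mean. Fdft1 and Hmgcs1 overlap exons of a gene on the opposite strand. Cholesterol efflux and lipid uptake genes were higher for 10 and lower for 9 of 25 (list adjusted p = 0.870). The lipid chaperone genes Fabp4 and Fabp5 fell from 14.4 ± 1.28 and 63.2 ± 4.33 to 0.487 ± 0.130 and 21.1 ± 1.98 FPKM, Gpnmb from 655 ± 74.7 to 204 ± 4.36, and Mylip, which degrades the LDL receptor, rose 5.37-fold. Matrix, protease and plaque genes were higher for 6 and lower for 6 of 17 (list adjusted p = 0.870). The protease genes Ctsk and Mmp14 fell from 102 ± 4.94 and 15.3 ± 2.31 to 23.7 ± 4.03 and 3.11 ± 0.121 FPKM, Mmp8 fell from 3.24 ± 0.360 to 0.0165 ± 0.0286 FPKM, and Vegfa rose 3.28-fold. Complement and coagulation genes were higher for 5 and lower for 3 of 12 (list adjusted p = 0.611). Serpinb2, a serpin gene, fell from 85.5 ± 24.8 to 6.75 ± 3.18 FPKM. C5ar1, the C5a receptor gene, rose 1.94-fold.

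Glycolysis and hypoxia genes were higher for 10 and lower for 7 of 25 (list adjusted p = 0.551), with Aldoc 2.87-fold and Pfkp 2.32-fold higher and Pgam1 at 0.627 of its control mean. Nuclear genes of mitochondrial respiration were higher for 5 and lower for 7 of 41, or 2 and 3 adjusted over the list alone (list adjusted p = 0.800). Sdhd fell from 114 ± 3.81 to 60.0 ± 4.59 FPKM. In the lists of adenosine, histone methyltransferase, clonal haematopoiesis, cholesterol efflux, matrix, complement, mitochondrial respiration and nuclear RNA genes, the median and the mean log2 fold change or the test differed in sign.

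Among the other large changes were rises of Aldh1b1, a mitochondrial aldehyde dehydrogenase gene, from 1.79 ± 0.236 to 34.7 ± 7.56 FPKM, and Nectin2, a cell adhesion gene, from 1.53 ± 0.290 to 29.9 ± 9.36 FPKM. The largest fall under the rule for named genes was that of Pdpn, which encodes the membrane glycoprotein podoplanin, from 102 ± 7.91 to 4.65 ± 0.622 FPKM (log2 fold change -4.19, SE 0.105, adjusted p = 8.37e-08). Npy, the neuropeptide Y gene, had 8.99 ± 0.805 FPKM in control and no read in SAHH-KO, which makes it at least 26.7-fold lower against a floor of 3 reads per library. Upp1, uridine phosphorylase, fell from 14.1 ± 1.74 to 2.23 ± 0.279 FPKM, the polycomb group gene Pcgf6 from 6.60 ± 0.232 to 0.653 ± 0.113 and the lectin receptor gene Clec4n from 8.26 ± 0.626 to 0.804 ± 0.0374 FPKM. The mitochondrial tRNA gene mt-Ty fell from 12.7 ± 2.36 to 1.25 ± 0.473 FPKM, and so short an RNA is poorly captured by such libraries.

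Most of the listed germline and developmental genes had no read. Of 30 germline genes silenced by DNA methylation 17 had no read in any library, 1 was tested, and that one, Rhox5, fell from 2.70 ± 0.446 to 0.902 ± 0.129 FPKM. Of 37 developmental polycomb targets 20 had no read and 4 were tested, of which Hoxb5 rose from 0.287 ± 0.120 to 1.55 ± 0.218 FPKM. Of 33 imprinted genes 15 had no read and 5 were tested (list adjusted p = 0.860). Impact fell to 0.649 of its control mean, and Nnat and Gnas lay at 1.22 ± 0.378 and 2.01 ± 0.620 FPKM in control against 2.23 ± 0.292 and 3.15 ± 0.306 FPKM in SAHH-KO (adjusted p = 0.0124 and 0.0311). Both missed the threshold without the filter on low genes, and Gnas also without SAHH-KO replicates 1, 2 or 3 in turn (adjusted p = 0.0993, 0.0632 and 0.0503).

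General macrophage genes were high in both groups. Of 23 tested, 11 were higher and 5 lower, or 12 and 6 adjusted over the list alone (list adjusted p = 0.163). Adgre1, which encodes F4/80, rose from 78.9 ± 1.77 to 165 ± 24.5 FPKM, the leukocyte gene Ptprc 1.91-fold and the Fc receptor gene Fcgr1 4.79-fold, and Cd33 fell from 3.85 ± 0.380 to 0.718 ± 0.369 FPKM. Of 24 markers of resident large peritoneal macrophages 8 had no read in any library, 4 were tested and 2 were lower, Serpinb2 and Icam2. Icam2 fell from 1.60 ± 0.252 to 0.861 ± 0.349 FPKM (adjusted p = 0.0224), a call lost without control replicates 1 or 3 or SAHH-KO replicates 1 or 2 (adjusted p = 0.0618, 0.0612, 0.0771 and 0.0687). Of 22 markers of monocyte-derived and small peritoneal macrophages 4 were tested: Itga4 and Clec4e were higher and Clec4n and Clec4d lower. Clec4e lost its call without SAHH-KO replicate 1 (adjusted p = 0.0561).

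Markers of other cells were few. The medians over all members in SAHH-KO ran from 0 to 0.0424 FPKM in 7 lists of other cell types. Dendritic cell markers were called higher, with 4 of 5 tested higher (list adjusted p = 0.0231, and adjusted p = 0.177 with an estimated correlation), Fscn1, Tcf4, Ccl22 and the interferon-inducible Bst2. The call was also lost without the filter on low genes (adjusted p = 0.388, median log2 fold change 0.02 against 0.76), and with voom the median was 1.21. Neutrophil markers were higher for 4 and lower for 2 of 6 (list adjusted p = 0.264), with Trem3 5.67-fold and Hdc 3.31-fold higher and S100a8 and Mmp8 lower. Of B cell markers Blnk was tested and rose 1.45-fold, of T and NK cell markers Il7r fell from 8.78 ± 0.612 to 2.81 ± 0.212 FPKM and Lck rose 1.73-fold, and of eosinophil, basophil and mast cell markers Hdc alone was tested. None of 25 mesothelial and fibroblast markers was. Of erythroid and platelet markers Bpgm was tested, at 1.62 ± 0.338 and 0.928 ± 0.240 FPKM (adjusted p = 0.0267), and it missed the threshold without control replicate 3 or SAHH-KO replicate 3 (adjusted p = 0.0987 and 0.0999).

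Ribosomal protein genes were higher for 42 and lower for 1 of 53 tested, and for 45 and 1 adjusted over the list alone (median 0.38, list adjusted p = 1.93e-07), a call lost with an estimated correlation (adjusted p = 0.362). Rps27, Rps23 and Rpl37 rose 1.69-fold, 1.43-fold and 1.48-fold. Many of these genes have pseudogene copies, and the median was 0.22 with TPM or assigned-read scaling and 0.18 with quantile normalization. Of 15 mitochondrially encoded RNAs none was higher and 2 were lower, none adjusted over the list alone (list adjusted p = 0.377). These were mt-Rnr2 and mt-Nd3, with adjusted p = 0.0155 and 0.0418, and both lost the call without SAHH-KO replicate 1 (0.0609 and 0.139), mt-Nd3 also without control replicate 2 or SAHH-KO replicate 2 (0.108 and 0.0529). Mitochondrial reads made up 1.99 ± 0.462% in control and 1.74 ± 0.0322% in SAHH-KO. Nuclear non-coding RNAs and histone genes were not called (adjusted p = 0.770), with 2 of 9 higher and 3 lower. Malat1 and Neat1, nuclear RNAs, rose 2.81-fold and 3.11-fold, and the histone gene Hist1h1c fell to 0.342 of its control mean.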

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

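Total-count scaling and voom on the recovered reads were chosen after the data were seen, as were the alternatives of genes named outside the rule. All other alternatives were set beforehand. Tools that need deposited counts were not run. Ahcy was lower and past the threshold under all 17 alternatives, with log2 fold changes from -2.17 to -1.84 and adjusted p from 7.51e-10 to 9.56e-05. Of 3506 values of 208 genes under the alternatives 3439 kept their direction and side of the threshold, 58 no longer passed, 9 passed only there, and 0 reversed. Of genes given in the text as counts only, Tlr7, Tnip3, Traf6, Nt5c2 and Rpl7a, lower members of lists, lost their calls without single libraries.

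Between 4438 and 5903 genes passed without 1 library (higher 2236 to 2934, lower 2199 to 2969, at least 2-fold 995 to 1186). With arrayWeights, whose library weights did not converge, 4154 genes were higher and 4373 lower, and the cause was not tested. The count of genes changed at least 2-fold was 793 with the stricter filter, which tests fewer genes, 1566 with voom and 1519 with a pseudocount of 0.1, and a threshold of 1.5-fold gave 2647. Voom called 5750 genes, 5383 of them in common with the main result and in the same direction. With the replicate number as a replicate block 5490 genes passed (2729 higher and 2761 lower) and the only change in the call of a named gene or list was that Csf1r passed (adjusted p = 0.0414). The deviations of equally numbered libraries correlated at r = 0.0955, 0.101 and -0.00556, and those of replicates 1 and 2 were the highest of all pairings. SAHH-KO replicate 3 correlated more with control replicate 1 (0.0206) than with its own number. These values neither show nor exclude a pairing by number.

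An estimated correlation left 2 lists called, and fry called 27. Under the estimated correlation the adjusted p was 0.177 for MHC class I, cholesterol biosynthesis, proliferation and dendritic cell markers. It was 0.0973 for Toll-like receptor and NF-κB genes, 0.0656 for classical effectors and NRF2 genes, 0.102 for stress response and p53 genes and 0.362 for ribosomal proteins. Without the filter the adjusted p was 0.0493 for DNA methylation genes, 0.0424 for cytokines, 0.0257 for the inflammasome list and 0.388 for dendritic cell markers, lists that then hold more genes near 0. The stricter filter gave 0.0460 for cytokines and for chemokines and 0.0243 for the inflammasome list. With TPM these were 0.0192 for cytokines and 0.0261 for the inflammasome, and with total-count scaling 0.0196 and 0.0268. Without 1 library the inflammasome list ranged from 0.0260 (without control replicate 2) to 0.0769. The cause of these list changes was not tested. The depth of 3 reads, worth 0.168 to 0.197 FPKM at 1 kb, limits genes near 0.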

Other observations

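The tests of scaling, stimulus, other cell types and depth given here, and the grouping of transcription factors by the families in the deposited table, were chosen after the results were seen. Genes named here that the rule for naming genes did not give were chosen after their values were seen. The counts over other splits of the libraries were set beforehand.

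Of 23 transcription factor families with at least 5 tested genes, the SAND family was higher in 7 of 7 genes (camera adjusted p = 0.00062, and adjusted p = 0.146 with an estimated correlation). Sp100, Sp110 and Sp140, nuclear body genes inducible by interferon, rose 4.21-fold, 7.65-fold and 5.07-fold. They lie next to each other on chromosome 1, so they need not be independent. AC168977.1, a clone-named gene on a scaffold outside the assembled chromosomes, rose 4.64-fold. The other members, Deaf1, Gmeb1 and Gmeb2, rose less, 1.68-fold, 1.28-fold and 1.56-fold. Interferon regulatory factors were higher in 6 of 7 (adjusted p = 0.00104, and adjusted p = 0.237 with an estimated correlation). Irf1 rose from 1.67 ± 0.134 to 22.03 ± 7.35 FPKM (SD, n = 3), Irf5 2.98-fold and Irf7 2.26-fold. STAT genes were higher in 5 of 6 (adjusted p = 0.00204, and adjusted p = 0.237 with an estimated correlation). Of 33 bZIP genes 18 were higher and 1, Jun, lower (adjusted p = 0.00143, and adjusted p = 0.146 with an estimated correlation). Batf2 rose from 1.31 ± 0.113 to 19.2 ± 2.10 FPKM, Atf3 1.82-fold and Atf4 1.81-fold. E2F genes were lower in 4 of 7 (adjusted p = 0.0148, and adjusted p = 0.293 with an estimated correlation), with E2f1 at 0.286, E2f8 at 0.163 and Tfdp1 at 0.467 of the control mean. ARID genes were higher in 6 of 13 (adjusted p = 0.0428, and adjusted p = 0.569 with an estimated correlation).

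The interferon-β gene Ifnb1 rose from 0.260 ± 0.226 to 2.82 ± 0.551 FPKM, with 10 reads in all control libraries and 100 in all SAHH-KO libraries. Ifnar1 and Ifngr1, which encode receptor chains for type I interferon and interferon-γ, rose 1.35-fold and 1.41-fold, but Ifnar1 missed the threshold with TPM (adjusted p = 0.0539) and with total-count scaling (adjusted p = 0.0581). In control, Irf1 and Gbp5, targets of interferon-γ, stood at 1.67 and 0.818 FPKM although all cultures had been given the cytokine. Cell-cycle genes fell, among them Mki67 from 35.98 ± 2.96 to 9.71 ± 0.958 FPKM and Top2a from 40.8 ± 3.70 to 11.9 ± 2.54 FPKM.

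Interferon-stimulated genes were higher in SAHH-KO. Scaling between libraries is argued against: over 4 other scalings, of which median-of-ratios factors nearly repeat the deposited scaling, the lowest median of the list was 2.38, with total-count scaling. A stronger stimulus in the SAHH-KO cultures may have raised these genes, and it cannot be told apart from an effect of the SAHH group, because no value here measures the stimulus that either group received and the labels do not give whether the groups were stimulated separately. In the cytokine list 6 members were lower and others higher. Such genes need not all rise with a stronger stimulus, so this count cannot decide, and a stronger stimulus stays open. An effect of lower SAHH stays open as the biological explanation, untested.

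Proliferation genes were lower in SAHH-KO. The highest median of the list over 4 other scalings was -1.60, with median-of-ratios factors, which nearly repeat the deposited scaling; over the 3 others it was -1.63, with quantile normalization, which argues against scaling. RNA from other cell types in the SAHH-KO libraries is argued against by the 7 marker lists, whose highest median was 0.0424 FPKM in SAHH-KO. Their most abundant genes were Bst2 at 531 FPKM and Lcn2 at 104.9 FPKM, and stimulated macrophages express both; Lcn2 also stands in the list of classical effectors. A biological difference of the SAHH group is left open and was not tested, and what the fall means rests on whether the cells were a dividing cell line, which is left open below.

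Most genes of the list of resident peritoneal macrophages were near 0 in all libraries, but Serpinb2 stood at 85.5 ± 24.8 FPKM in control and 6.75 ± 3.18 FPKM in SAHH-KO and Cd9 at 169 and 159 FPKM. Timd4, Gata6 and Vsig4 of that list had 0 reads, as had Ciita, H2-Aa, H2-Eb1, Cd163, Retnla and Chil3, while Pycard had 11 reads over all 6 libraries. In the list of monocyte-derived and small peritoneal macrophages, Ly6c2, F13a1, Plac8 and Ear2 also had 0 reads. Its tested genes Clec4d, Clec4e, Itga4 and Clec4n stood at 293, 319, 12.2 and 8.26 FPKM in control. Lyz2, Cd68 and Csf1r, general macrophage genes, stood at 5653, 595 and 106.8 FPKM in control and at 6616, 614 and 90.97 FPKM in SAHH-KO. Depth is argued against, because 3 reads of a gene of the resident list were worth at most 0.265 FPKM. That list describes resident cells and the labels name elicited ones, so its low values alone cannot decide which cells these were. Cells other than those the labels name, such as a dividing cell line, may be the source: 5 of the genes, Serpinb2, Cd9, F10, Icam2 and Fabp7, reached 1 FPKM, Pycard is known to be absent from a widely used mouse macrophage line, and Mki67 and Top2a stood at 35.98 and 40.8 FPKM in control; it stays open because elicited macrophages processed alike were not analysed here; no biological explanation was tested.

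With 6 libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 5518 changed genes and the highest other split 0 with limma, where up to 245 genes had an unadjusted p under 0.05. It gave 1094 genes changed at least 2-fold, against 0. As large a result occurred in 1 split, the real one, for either count, and in 2 splits for the lists called, where the real split gave 12 and another 13. With an estimated correlation these were 2 and 0. Each of the 9 other splits also called the interferon and proliferation lists, with medians of at most 0.94 and 0.71 in size. Each of them sets 2 libraries of a group and 1 of the other against the reverse, so part of the group difference remains. They are therefore not a clean null for these lists or for the counts of genes. In the gene test that difference also adds to the spread within the mixed groups, which works against calls. The 0 calls there thus cannot show what chance alone would give.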
